A study of Mus musculus with 96 samples.

How the data were processed

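RNA of 96 single mouse preoptic neurons was amplified and sequenced after patch-clamp recording, per the labels' protocols. The authors deposited a table of whole-number read counts per gene and cell and a table of normalized signal values for the same genes and cells. The submitters' processing notes name FastQC, STAR and edgeR and the build mm10, without versions; the annotation, the counting step and whether strand was used are not given in the sources used here. In the deposited normalized signal table each cell's values equal its counts divided by its total and by a constant factor, from 0.177 to 2.49 over cells; how these factors were made is not given in the sources used here. Reads of overlapping or near-identical genes cannot be told apart from these counts. Mitochondrially encoded genes were not analysed here. The results of some named and listed genes, among them 1 used to weigh oligodendrocyte RNA, are not reported here.

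Groups follow the temperature class in the labels. The 18 cells labelled as unknown entered no comparison. Because no label names an animal, a group counts as 1 sample, so values are descriptions without tests. A cell entered with at least 100000 counts and 1000 genes, which all 96 cells met. The table holds 24054 genes, of which 7772 had no count in any cell, and no 2 cells held identical values; the highest correlation of log values between cells was 0.646.

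Counts were divided by the cell's total over all genes, Rn45s included, and multiplied by 1000000 (CPM). A gene counted as detected at 10 CPM or more; shares have exact Clopper-Pearson 95% intervals. Differences are of the mean over cells of log2(CPM + 1), a scale that understates changes of low genes. Summed counts have exact Poisson 95% intervals. Genes were eligible at 10 CPM or more in at least 25% of the cells, and at least 3 cells, of either group. Named genes are eligible genes whose share and log2 differences agree in sign and whose log2 difference keeps at least 2/3 of its size when any 1 cell is left out, ranked by that difference. The number taken per direction was 12, 10, 5, 8, 5 and 8 in the order all sensitive, warm-sensitive, cold-sensitive, silent sensitive, warm against cold, and silent against other cells. Predicted genes, ribosomal protein genes and clone names were left out of the ranking. A set of 19 genes of transmitters, thermosensing and preoptic identity could be named in any comparison. Gene lists were fixed in advance, and a list's median was placed among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries.

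Alternatives fixed before the data were examined were detection at 1 or 5 counts, pseudocounts of 0.1 and 10 CPM, TMM library sizes, the deposited normalized values, totals without ribosomal protein genes, DESeq2 size factors, no or a stricter cell filter, thinning to 100000 counts, summed counts, equal weight for silent and other cells, no limit on low genes, and leaving out each cell. Added after seeing the data were totals without Rn45s, differences relative to the median gene, differences within the letter in the cell's title, thinning to 200000 counts outside Rn45s, leaving out cells with over 75% of counts in Rn45s, and summed counts of Ptgds with each cell left out. The letter is treated as a possible batch because quality differed along it; what it stands for is not given in the labels. The measures were tested on simulated data with 200 genes changed 2-fold or 4-fold. In the same order of comparisons, the direction came out right for 83%, 82%, 72%, 70.7%, 64.9% and 86% of the eligible genes changed 2-fold and for 97%, 88%, 87.8%, 83.5%, 84.2% and 98% of those changed 4-fold. In these simulated data unchanged genes had a median difference of -0.0019 for all sensitive and -0.052 for warm-sensitive cells. In the real data the median gene differed by -0.98 and -1.36. Simulated genes changed 2-fold were found at a median of 0.76 and 0.94, smaller in size than these shifts. The percentages therefore hold for simulated data without such a shift and do not give the accuracy of the real comparisons. Changes were simulated only in genes well above 10 CPM in summed counts, so the percentages do not cover genes near that limit. Empty cells were drawn for each gene independently, without cells of poorer quality. For all sensitive cells this made 6644 genes eligible, against 3733 in the real data. Coordinates are from GENCODE M21 on mm10. Software was R 4.3.3, edgeR 4.0.16, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.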

Results

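The series holds single neurons of the mouse preoptic area, a hypothalamic region that takes part in the control of body temperature. Each cell was recorded by patch clamp in a brain slice, then picked with a glass pipette, and its RNA was sequenced (Patch-seq), to find genes that mark temperature-sensitive neurons. The labels sort 78 cells by their response to temperature: 21 warm-sensitive, 5 cold-sensitive, 24 insensitive, 10 silent sensitive and 18 silent insensitive cells. A further 18 cells carry no such class and entered no comparison. No label names an animal, slice or day, so each group counts as 1 sample, no test was made and no p-value is given. Intervals are exact and cover counting error only: those of shares treat cells as independent draws and leave out any variation between animals, and those of summed counts treat reads as independent molecules, which they are not.

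Total counts ran from 465167 to 3660726 per cell, with a median of 1279600. A single gene, Rn45s, the precursor of ribosomal RNA, took 53.2% of all counts. Its median share was 45.4% in insensitive, 67.7% in warm-sensitive, 56.1% in cold-sensitive, 55% in silent insensitive and 61.8% in silent sensitive cells. Median counts outside Rn45s were 761928 in insensitive and 314892 in warm-sensitive cells. The median number of genes with a count was 4022 in insensitive, 3244 in warm-sensitive, 4645 in cold-sensitive, 3668.5 in silent insensitive and 3230 in silent sensitive cells. In every comparison the median gene was lower in the group named first, so differences are also set against the median gene. Some differences are also given within title letters, that is between cells whose titles carry the same letter, treated as a possible batch. A gene list is said to stand high or low where its median lies in the outer 2.5% of random lists on that side, and the settings that end this are counted beside it with the range of percentiles over settings. Not every setting could end it. Leaving out the cell filter changes nothing, since all cells met it, and centring on the median gene moves all genes alike. Counts of settings can therefore overstate how steady a list is.

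**Figure D1:**
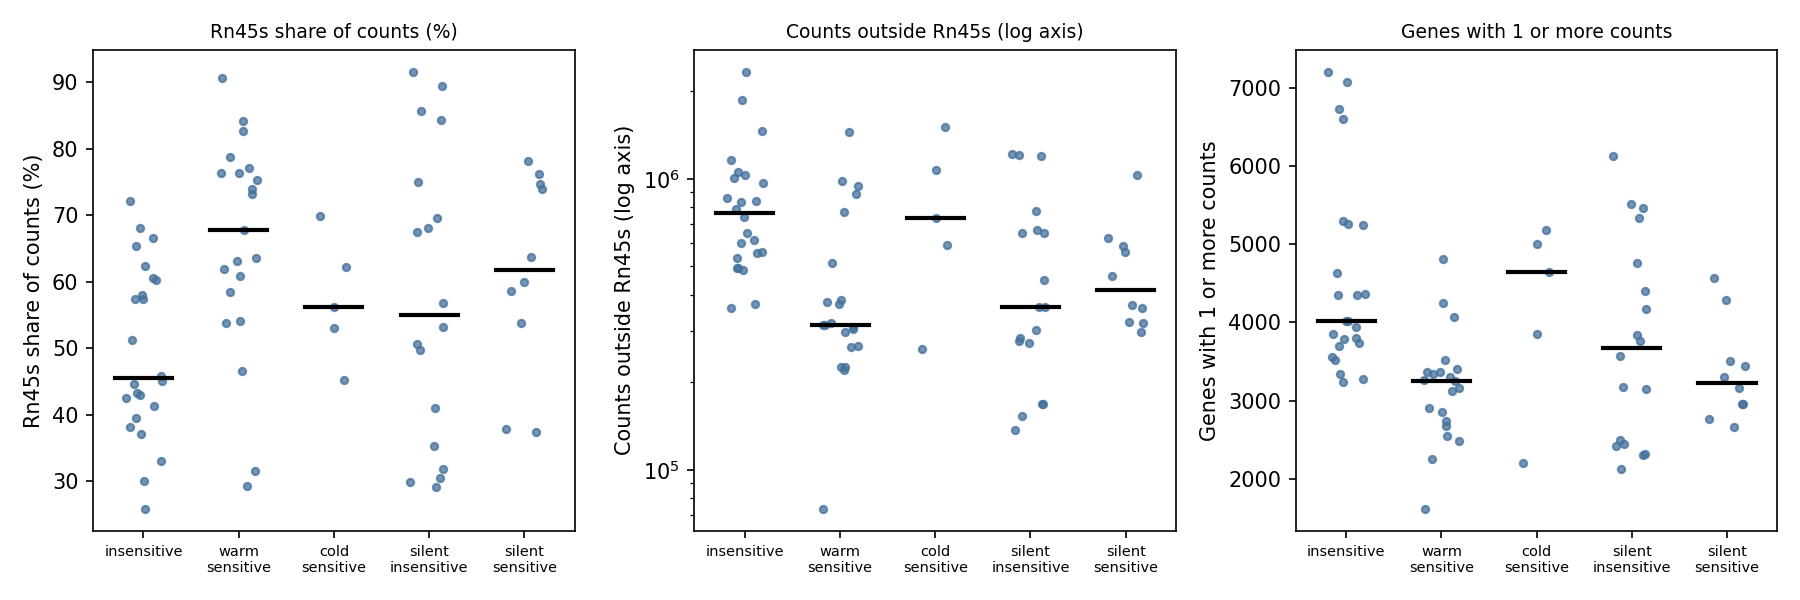
Each point is 1 cell and each bar the median of its group, for the share of counts in Rn45s (%), the counts outside Rn45s (log axis) and the number of genes with 1 or more counts. Warm-sensitive cells had the highest median Rn45s share, 67.7%, and a median of 3244 genes.

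The first comparison set all 36 temperature-sensitive cells against all 42 insensitive ones. Gltp, a glycolipid transfer protein, was highest relative to insensitive cells, with a difference of 1.43 on the log2(CPM + 1) scale and 41.7% and 26.2% of cells at 10 CPM or more. Plcg1, a phospholipase, was at 25% and 7.14%, and Gabbr1, a subunit of the metabotropic GABA receptor, at 47.2% and 33.3%. Rangap1, which activates the GTPase Ran, was lowest, at 22.2% (95% interval 10.1 to 39.2%) against 73.8% (58 to 86.1%), a difference of -3.68 or -2.70 relative to the median gene. Dctn3, a dynactin subunit, differed by -3.62, Stub1, a ubiquitin ligase, by -3.41, and Camk2a, a neuronal kinase, by -2.94. Within title letters Gltp differed by 1.73 and Rangap1 by -3.49. The 12 higher genes ranged from 0.95 to 1.43 and the 12 lower ones from -3.68 to -2.90. Rangap1 lies on chromosome 15, 81704248 to 81745530 and Gltp on chromosome 5, 114669398 to 114690984 of mm10.

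Ptgds, which encodes a prostaglandin D synthase (chromosome 2, 25466709 to 25470046), was at 10 CPM or more in 100% and 92.9% of sensitive and insensitive cells, with a difference of 0.85; summed over cells it was 3549 CPM (3532 to 3566) against 3595 CPM (3580 to 3610). Single cells decide that sum: without insensitive cell 2 the insensitive sum was 2048 CPM, and without silent sensitive cell 7 the sensitive sum was 2397 CPM. The list called voltage-gated sodium channel genes also holds Fgf genes, Fgf12 and Fgf13 among them, which encode no channel. Among the fixed lists, voltage-gated sodium channel genes stood high (median difference -0.0042, 7 of 8 members above the median gene, percentile 99.98, not so in 1 of 18 settings, range 79.6 to 99.99), as did GABA receptor genes (median difference -0.24, 8 of 10 members above the median gene, percentile 99.96, not so in 3 of 18 settings, range 89.6 to 99.98) and the GABAergic list (median difference -0.12, 3 of 3 members above the median gene, percentile 98.7, not so in 7 of 18 settings, range 77.5 to 99.9). Oligodendrocyte markers (median difference 0.34, 4 of 4 members above the median gene, percentile 99.98) and microglia markers (median difference -0.32, 8 of 9 members above the median gene, percentile 99.3, not so in 3 of 18 settings, range 81.5 to 99.99) also stood high, and Apod, an oligodendrocyte marker, is among the named genes. Among cells that were not silent and among silent cells, percentiles were 97.2 and 93.8 for sodium channel genes, 68.1 and 97.53 for GABA receptor genes, 99.6 and 60.1 for the GABAergic list, 100 and 66 for oligodendrocyte and 99.97 and 39.6 for microglia markers. The GABAergic medians were 0.32 and -0.41, and the oligodendrocyte ones 0.85 and -0.20. Nuclear genes of oxidative phosphorylation stood at percentile 67.5 and pan-neuronal genes at 49.5. The median of sodium channel genes was -0.20 without silent sensitive cell 8 and 0.089 without silent insensitive cell 7. The median of GABA receptor genes was -0.41 without warm-sensitive cell 12 and -0.16 without insensitive cell 14. The median of the GABAergic list was -0.31 without warm-sensitive cell 12 and 0.014 without silent sensitive cell 5, and the list left the outer 2.5% without 12 of 78 cells, each left out alone. The median of oligodendrocyte markers was 0.14 without warm-sensitive cell 17. The median of microglia markers was -0.54 without silent sensitive cell 6 and -0.14 without silent insensitive cell 1, and the list left the outer 2.5% without 1 of 78 cells, each left out alone. Over the 3733 eligible genes the median difference was -0.98, with 292 genes higher and 3441 lower.

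**Figure D2:**
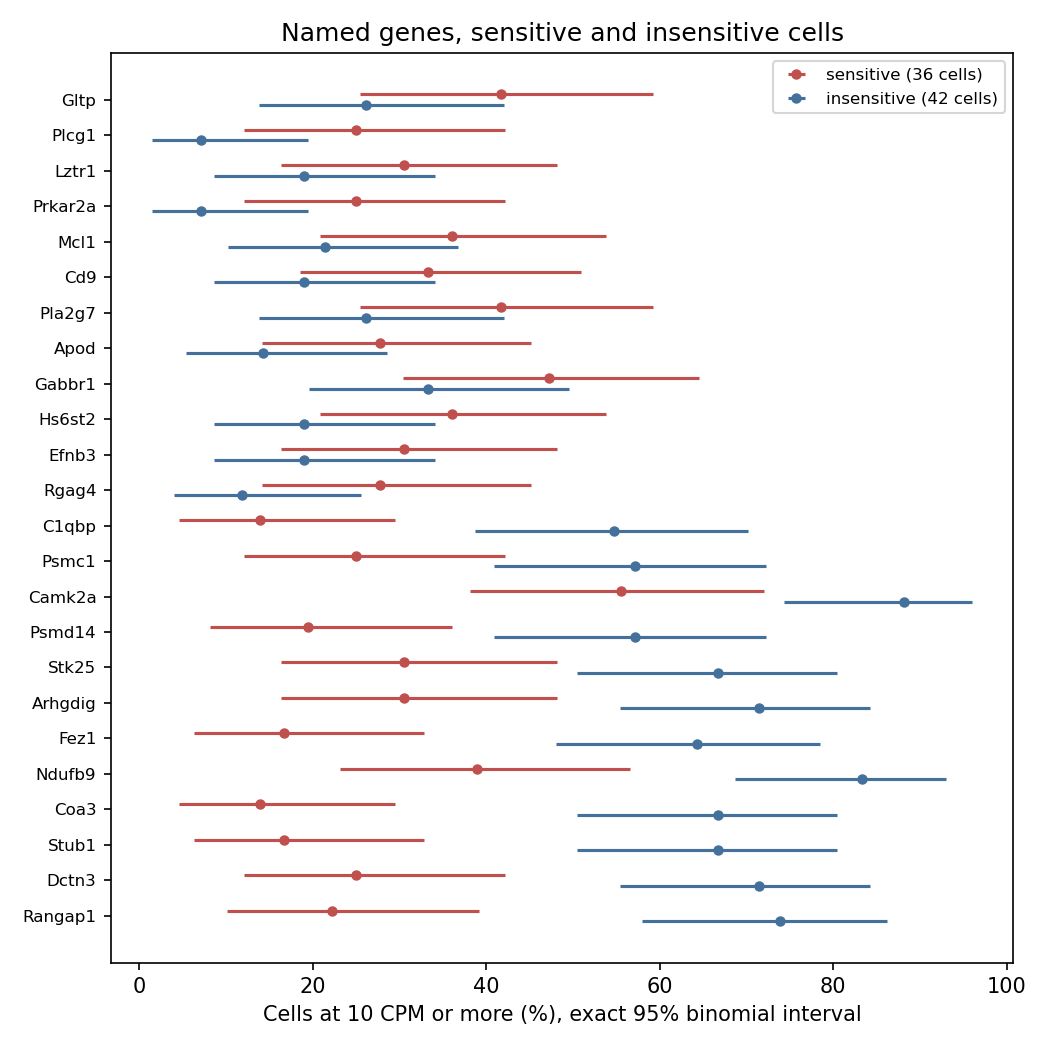
Share of cells at 10 CPM or more (%) for the 24 named genes in sensitive (36) and insensitive (42) cells; points are shares and bars exact 95% binomial intervals. Rangap1 was at 22.2% and 73.8% and Gltp at 41.7% and 26.2%.

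Warm-sensitive cells were set against insensitive cells that were not silent. Gad1, which makes GABA (chromosome 2, 70553072 to 70602014), was higher, at 61.9% (95% interval 38.4 to 81.9%) against 50% (29.1 to 70.9%), a difference of 1.31. Pla2g7, a phospholipase, was at 52.4% and 25%, and Fasn, the fatty acid synthase, at 47.6% and 33.3%. Ndufb9, a subunit of respiratory complex I (chromosome 15, 58933756 to 58939488), was lowest, at 23.8% (95% interval 8.22 to 47.2%) against 95.8% (78.9 to 99.9%), a difference of -4.98 or -3.61 relative to the median gene. Fez1, which takes part in axonal transport, was at 0% and 70.8%, and Cs, the citrate synthase, at 14.3% and 75%. In silent sensitive against silent insensitive cells Cs differed by 0.50, while Ndufb9 and Fez1 were lower there too. The list of nuclear genes of oxidative phosphorylation was at percentile 80.6 for warm-sensitive cells, with 9 of 17 members above the median gene. Within title letters Gad1 differed by 0.89 and Ndufb9 by -4.50. The 10 higher genes ranged from 1.25 to 1.86 and the 10 lower ones from -4.98 to -4.21.

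The GABAergic list stood high in warm-sensitive cells (median difference 0.85, 3 of 3 members above the median gene, percentile 99.99), although only 3 of its 11 genes were eligible, 2 of them higher and 1 lower. Gad2 was at 47.6% and 58.3%, and Slc32a1, the vesicular GABA transporter, which was not eligible, at 14.3% and 12.5%. Genes of preoptic transcription factors stood low in a minority of settings (median difference -2.09, 1 of 4 members above the median gene, percentile 0.77, not so in 12 of 17 settings, range 0.56 to 90.8). Oligodendrocyte (median difference 0.78, 4 of 4 members above the median gene, percentile 99.99), astrocyte (median difference -0.46, 4 of 5 members above the median gene, percentile 97.8, not so in 7 of 17 settings, range 72.3 to 99.6) and microglia markers (median difference -0.67, 8 of 9 members above the median gene, percentile 99, not so in 3 of 17 settings, range 10.1 to 99.9) stood high as well. The potassium channel gene Kcnk2 was at 0% and 33.3%, Bdnf at 0% and 25%, Trpc5 at 0% and 25% and Slc17a6, a vesicular glutamate transporter, at 38.1% and 50%; with 0 of 21 cells, a share of up to 16.1% stays possible. Slc17a6 differed by -1.39, and by -0.63 within title letters. Relative to the median gene Kcnk2 differed by -0.50, Bdnf by -0.43 and Trpc5 by 0.013. Trpm2, a channel gene, was at 9.52% and 8.33%, and no cell of either group reached 10 CPM of Ptger3, Trpv1 or Trpm8. Ptgds differed by 0.89 in the mean of log values but was lower in summed counts, 1900 CPM (1883 to 1916) against 5227 CPM (5205 to 5249). Without insensitive cell 2 the latter was 2886 CPM, and without warm-sensitive cell 5 the former was 1239 CPM. Insensitive cell 14 held 37875 CPM of Ptgds, beside 37958 CPM in cell 2. The insensitive sum was not taken without both, so the lower sum in warm-sensitive cells may rest on these cells. The median of the GABAergic list was 0.55 without warm-sensitive cell 8. For preoptic transcription factor genes the list left the outer 2.5% without 2 of 45 cells, each left out alone. The median of oligodendrocyte markers was 0.40 without warm-sensitive cell 17. The median of astrocyte markers was -0.83 without warm-sensitive cell 8 and -0.14 without insensitive cell 14, and the list left the outer 2.5% without 18 of 45 cells, each left out alone. The median of microglia markers was -0.39 without insensitive cell 5, and the list left the outer 2.5% without 13 of 45 cells, each left out alone. Over the 4601 eligible genes the median difference was -1.36, with 235 genes higher and 4366 lower.

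**Figure D3:**
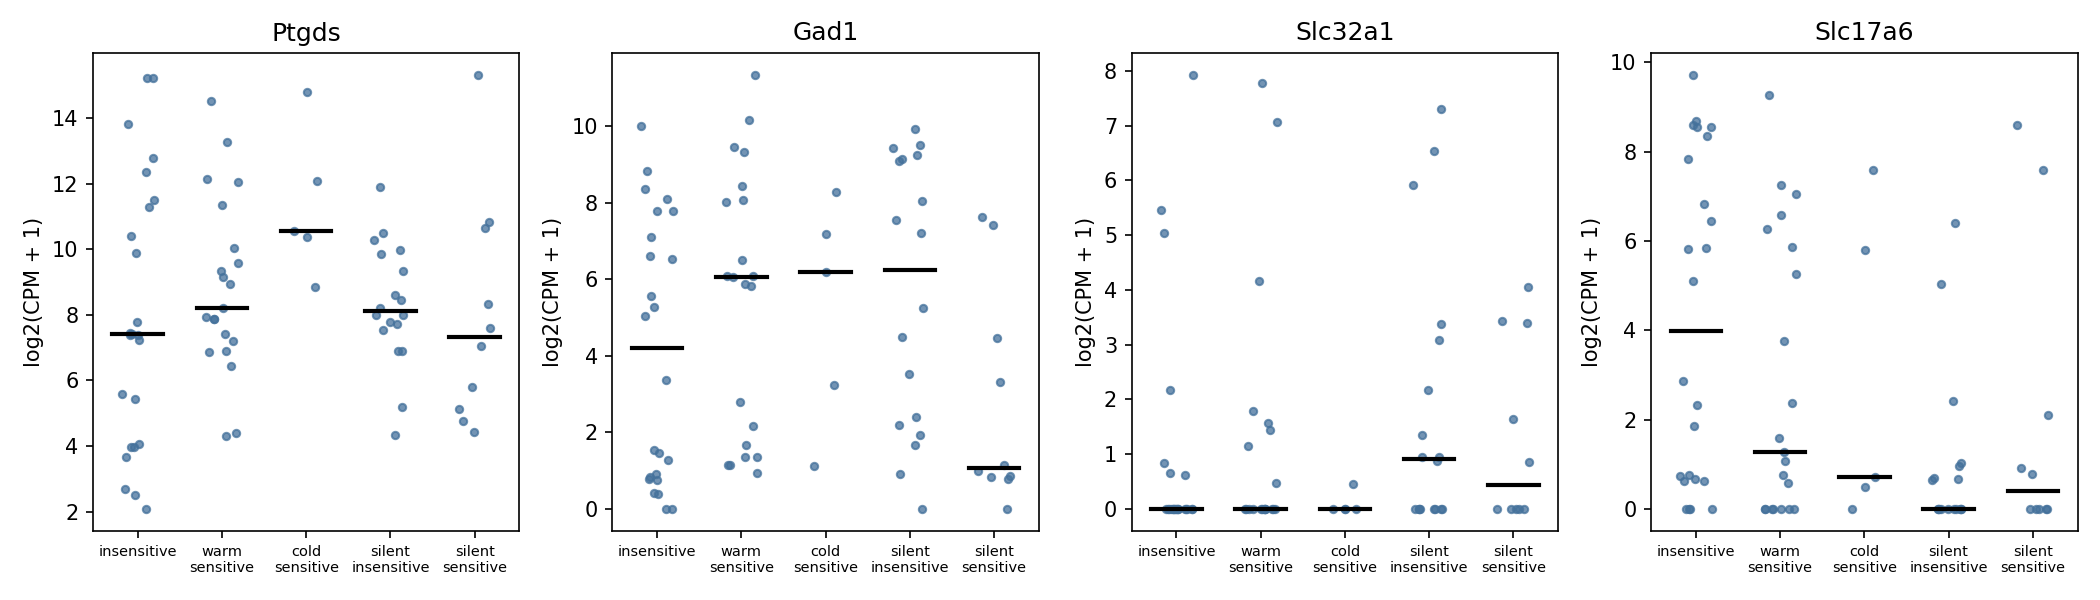
Each point is 1 cell and each bar the median of its group, in log2(CPM + 1), for Ptgds, Gad1, Slc32a1 and Slc17a6. Median Ptgds was 10.56 in cold-sensitive, 8.22 in warm-sensitive and 7.40 in insensitive cells.

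The 5 cold-sensitive cells were set against the same insensitive cells. Fgf13, an intracellular factor that binds sodium channels, was at 100% (95% interval 47.8 to 100%) against 16.7% (4.74 to 37.4%), a difference of 5.27, or 5.20 within title letters; the gene lies on chromosome X, 59062145 to 59568071. Snx5, a sorting nexin, was at 100% and 33.3%. Msmo1, an enzyme of sterol synthesis, was at 0% and 62.5% and Map6, which binds microtubules, at 0% and 62.5%, where 0 of 5 cells allow up to 52.2%. Ptgds was at 100% and 87.5% with a difference of 3.37, and summed counts gave 6166 CPM (6116 to 6217) against 5227 CPM (5205 to 5249). Without cold-sensitive cell 1 the cold-sensitive sum was 1648 CPM, which turns the direction, and without insensitive cell 2 the insensitive sum was 2886 CPM. Insensitive cell 14, at 37875 CPM of Ptgds, stayed in that sum. Microglia markers (median difference 1.73, 9 of 9 members above the median gene, percentile 99.97) and oligodendrocyte markers (median difference 2.34, 4 of 4 members above the median gene, percentile 99.99, not so in 1 of 17 settings, range 96.1 to 100) stood high beside it. The median of microglia markers was 0.80 without cold-sensitive cell 1 and 2.98 without cold-sensitive cell 3. The median of oligodendrocyte markers was 1.37 without cold-sensitive cell 1. Over the 4644 eligible genes the median difference was -0.52, with 1599 genes higher and 3045 lower. Without cold-sensitive cell 4 that median was -0.050.

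Warm-sensitive and cold-sensitive cells were also set against each other. Ddost, a subunit of the oligosaccharyltransferase, was at 42.9% and 0%, Msmo1 at 33.3% and 0%, and Itih3 at 28.6% and 0%; 0 of 5 cells allow up to 52.2%. Psmd14, a proteasome subunit, was at 9.52% (95% interval 1.17 to 30.4%) against 100% (47.8 to 100%), a difference of -6.87 or -6.31 within title letters, and Uqcrfs1, a subunit of respiratory complex III, at 23.8% and 100%. Astrocyte markers stood high in warm-sensitive cells (median difference 1.30, 2 of 3 members above the median gene, percentile 99.3, not so in 2 of 17 settings, range 97 to 99.98), whereas voltage-gated potassium channel genes did so in few settings (median difference 0.24, 4 of 5 members above the median gene, percentile 98.2, not so in 14 of 17 settings, range 81.5 to 98.6). The median of astrocyte markers was 0.78 without cold-sensitive cell 3 and 2.39 without cold-sensitive cell 2, and the list left the outer 2.5% without 2 of 26 cells, each left out alone. The median of potassium channel genes was -0.36 without cold-sensitive cell 4 and 0.67 without cold-sensitive cell 3, and the list left the outer 2.5% without 13 of 26 cells, each left out alone. Over the 2199 eligible genes the median difference was -1.56, with 424 genes higher and 1775 lower.

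Among cells labelled as silent, the 10 sensitive cells were set against the 18 insensitive ones. Gad1 was lower in the sensitive cells, at 30% (95% interval 6.67 to 65.2%) against 66.7% (41 to 86.7%), a difference of -2.89 or -3.92 within title letters. Phactr1, which binds actin and protein phosphatase, was at 70% and 16.7%, and Tppp3 at 90% and 50%. Csnk2b, a casein kinase subunit, was at 0% (95% interval 0 to 30.8%) against 61.1% (35.7 to 82.7%), and Map1lc3b, a protein of autophagosomes, at 0% and 66.7%. Neuropeptide and granin genes stood high (median difference 0.44, 11 of 12 members above the median gene, percentile 98.9, not so in 3 of 17 settings, range 94.9 to 99.96), as did GABA receptor genes (median difference 0.37, 7 of 9 members above the median gene, percentile 97.53, not so in 8 of 17 settings, range 90.7 to 99.4), while Ptgds differed by -0.32, and by 0.91 within title letters. The median of neuropeptide and granin genes was 0.044 without silent sensitive cell 8 and 0.76 without silent insensitive cell 7, and the list left the outer 2.5% without 2 of 28 cells, each left out alone. The median of GABA receptor genes was -0.11 without silent sensitive cell 3 and 0.69 without silent sensitive cell 9, and the list left the outer 2.5% without 14 of 28 cells, each left out alone. Over the 3459 eligible genes the median difference was -0.65, with 1062 genes higher and 2397 lower.

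The 28 silent cells were set against the 50 others. Slc17a6 (chromosome 7, 51622006 to 51671119) was at 14.3% (95% interval 4.03 to 32.7%) against 44% (30 to 58.7%), a difference of -2.14 or -1.84 relative to the median gene and -2.21 within title letters. Calb1, the calcium-binding calbindin, was at 39.3% and 64%, and Pnck, a calmodulin-dependent kinase, at 32.1% and 74%. Trh, which encodes thyrotropin-releasing hormone, was at 35.7% and 14%, and Mobp, a myelin gene, at 71.4% and 42%. Oligodendrocyte (median difference 0.53, 3 of 4 members above the median gene, percentile 99.7, not so in 5 of 17 settings, range 49.9 to 99.98) and astrocyte markers (median difference 0.74, 4 of 5 members above the median gene, percentile 99.4, not so in 5 of 17 settings, range 53.6 to 99.9) stood high in silent cells, as did genes of preoptic transcription factors (median difference 1.004, 2 of 3 members above the median gene, percentile 99, not so in 6 of 14 settings, range 42.6 to 99.7). Pan-neuronal genes had a median difference of -0.78, with 11 of 12 members lower and 9 below the median gene, at percentile 3.72 and 2.31 to 9.23 over settings. The median of astrocyte markers was 0.49 without silent insensitive cell 4, and the list left the outer 2.5% without 1 of 78 cells, each left out alone. For preoptic transcription factor genes the list left the outer 2.5% without 3 of 78 cells, each left out alone. Over the 3481 eligible genes the median difference was -0.29, with 1193 genes higher and 2288 lower.

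The difference between sensitive and insensitive cells was then compared between cells that were not silent and cells that were, which share no cell. Across the 3049 genes eligible in both, Pearson's r was 0.0738 and Spearman's rho 0.0666, across genes, which are not independent replicates. Of these genes 52.2% lay on the same side of the median gene in both. Of the 10 genes named as higher in warm-sensitive cells, 5 lay above the median gene in the silent comparison, and of the 10 named as lower 8 lay below it. Psmd14 was lower in both, by -2.89 and -3.77, while Gad1 differed in direction, at 1.27 and -2.89. The Psmd14 value of -2.89 pools 2 groups that went opposite ways. Against insensitive cells Psmd14 was lower in warm-sensitive cells, by -4.21, and higher in cold-sensitive ones, since warm-sensitive minus cold-sensitive was -6.87. Psmd14 was also named as lower in both the warm-sensitive and the silent ranking, so its agreement was set by that choice.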

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

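Tests of thinning, title letter and scaling for genes per cell, and of oligodendrocyte RNA and single cells for Ptgds, were chosen only after those results or closely related ones had been seen. The rule for oligodendrocyte RNA was also made stricter after its first outcome. The bounds of the Gad1 tests were written before the Gad1 values under those settings were looked at. Silent sensitive cell 1 held 1026836 counts outside Rn45s, farther from the other 9 cells than Dixon's criterion allows; with values of 5 measures in each of 2 groups checked this way, chance marks about 1 in 20 sets of values. Of the 18 cells without a temperature class, 17 had Snap25, a neuronal gene, at 10 CPM or more, so they hold neuronal RNA that no comparison used. Among the labelled cells, insensitive cell 19, silent insensitive cell 15 and silent sensitive cell 9 lay below that level, at 7.78, 7.45 and 8.87 CPM.

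Warm-sensitive cells held fewer genes than insensitive ones. Thinning 20 and 24 cells to 200000 counts outside Rn45s left 100% of the gap in medians, 770.5 genes; 5 other draws gave 757 to 818.5, and the gap in means kept 81.1%, which argues against depth as the whole cause. Within title letters 96.8% of the difference in means was left, and with totals taken without Rn45s 93.6% of the median gene's difference; with DESeq2 size factors that difference was -0.52 instead of -1.36. RNA quality or yield of each recording was not tested and may differ between groups, since cells of 1 group can share an animal or a day that the labels do not name.

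Ptgds was higher in cold-sensitive and, less so, warm-sensitive cells in the mean of log values. In summed counts it was not higher in warm-sensitive cells, nor in cold-sensitive cells without cell 1. The insensitive sum holds insensitive cell 2, at 37958 CPM, and insensitive cell 14, at 37875 CPM. It was not taken without both, so the direction in summed counts is not settled. RNA of oligodendrocytes, which also express Ptgds, cannot be told apart as a source. Relative to the median gene their list of 4 eligible markers stood 2.86 higher in cold-sensitive and 2.14 higher in warm-sensitive cells. Ptgds itself stood 3.89 and 2.25 higher on that scale, so the list reached 73.5% and 95% of its difference. The abundant marker Mbp was at 2184 against 853 CPM in summed counts of the 5 cold-sensitive cells. In those of warm-sensitive cells Mbp was at 846 against 853 CPM. Before centring the list's median was 2.34 in cold-sensitive cells and 1.37 without cell 1, and 0.78 in warm-sensitive cells and 0.40 without cell 17. Mbp also rests on single cells: it was 850 CPM without cold-sensitive cell 1, and 577 CPM in insensitive cells without cell 2. Without cold-sensitive cell 1, 74.4% of the Ptgds difference in log values was left and its summed counts fell below those of insensitive cells, which with 5 cells leaves open how far it rests on that cell.

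Gad1 was higher in warm-sensitive and lower in silent sensitive cells than in their insensitive counterparts. Thinned outside Rn45s the differences were 1.91 and -2.53, with at least 87.4% of each size left, and within title letters 0.89 and -3.92, with at least 68%. Thinning left 20 and 24 cells in the first comparison and 10 and 14 in the second, so the 87.4% also reflects the cells dropped. Warm-sensitive cells held fewer counts outside Rn45s than insensitive ones (medians 314892 and 761928) yet more Gad1, so thinning was unlikely to remove that difference. In silent sensitive and silent insensitive cells the medians were 415420 and 362457, but the means 493498 and 517066. The bound set for Gad1 was opposite signs with 50% of each size left. At the 75% used for genes per cell, the 68% would leave title letter open. At its own looser bound, neither depth nor title letter alone accounts for the opposite directions of Gad1. Other GABAergic genes do not show them as clearly: Gad2 was lower in both, by -0.55 and -0.41, and Slc32a1 differed by 0.26 and -0.47, so the pattern is one of Gad1 and chance sampling of cells stays open. The difference between the 2 comparisons was not tested.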

How the results depend on the processing

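The settings with Rn45s, the median gene, the title letter, cells over 75% Rn45s or summed counts with cells left out were chosen after seeing the data. Every gene named by rank kept its direction under every setting run; since these genes were picked as the most extreme, that says little about other genes. Which genes are named was less steady than their direction: without cells over 75% Rn45s, 14 of 24 genes were still named for all sensitive, 7 of 20 for warm-sensitive, 7 of 16 for silent sensitive, 4 of 10 for warm against cold and 7 of 16 for silent against other cells. Thinned outside Rn45s, 6, 5 and 9 were still named in the last 3 of these, and with totals without Rn45s 6 of 10 for warm against cold. Leaving out cells over 75% Rn45s fell unevenly on the groups. It kept 13 of 21 warm-sensitive and all 24 insensitive cells, and 26 of 36 sensitive against 38 of 42 insensitive cells with silent ones included. The median difference moved by over 1.5 times at a pseudocount of 10 CPM to -0.51 (all sensitive), -0.69 (warm-sensitive), -0.31 (cold-sensitive), -0.37 (silent sensitive), -0.81 (warm against cold), -0.15 (silent against other); with DESeq2 size factors to -0.19 (all sensitive), -0.52 (warm-sensitive), -0.29 (cold-sensitive), 0.30 (silent sensitive), -0.26 (warm against cold), -0.043 (silent against other), the silent sensitive value changing sign; with summed counts to -0.48 (all sensitive), -0.85 (warm-sensitive), -0.40 (warm against cold), -0.19 (silent against other); with TMM library sizes to -0.29 (cold-sensitive), -0.43 (silent sensitive); with the deposited values to -0.33 (cold-sensitive), -0.33 (silent sensitive); with detection at 1 count to -0.42 (silent sensitive), -0.87 (warm against cold); thinned outside Rn45s to -1.02 (silent sensitive), -1.01 (warm against cold), -0.066 (silent against other); and without cells over 75% Rn45s to -1.18 (silent sensitive), -0.79 (warm against cold). For cold-sensitive cells it was -0.79 without cold-sensitive cell 3 and -0.050 without cold-sensitive cell 4, the range over cells left out; in the other comparisons no single cell moved it by over 1.5 times. Spearman's rho between the silent and other comparisons was 0.105 when thinned outside Rn45s.

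Among differences that kept at least 2/3 of their size when any cell was left out, signs changed for a few genes. For all sensitive cells Gad2 was 0.0033 with the deposited values, 0.53 with DESeq2 size factors, 0.58 in summed counts, 0.55 relative to the median gene and 0.054 thinned outside Rn45s. Adcyap1 was 0.15 with DESeq2 size factors, 0.38 in summed counts and 0.45 relative to the median gene. Ptgds in summed counts was -0.019 for all sensitive and -1.46 for warm-sensitive cells. With each cell left out as well, it ran from -0.58 to 0.79, from -2.08 to -0.60 and, for cold-sensitive cells, from -1.67 to 1.10. With 1 cell left out, insensitive cell 2 or cell 14 always stays in the sum, so these ranges do not show how steady it is. Trpc5 in warm-sensitive cells was 0.013 relative to the median gene. In these settings the cause was not tested, except that centring moves every gene by the median by construction. Less steady differences of the fixed set changed sign in 54 cases. Of the other gene values, 2068 stayed within 1.5 times and 423 moved further, those 54 included; list percentiles left the outer 2.5% in 80 cases and entered it in 68. No paired analysis was possible because cell numbers follow accession order only and no label pairs cells. Depth limits low genes most: for a gene seen in no cell of a group, these counts do not tell low expression from absence.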

Other observations

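The 18 cells without a temperature class held 756016 to 3660726 counts, with a median Rn45s share of 42.2% and a median of 4187 genes. Ptgds ranged in them from 0.948 to 58710 CPM, with a median of 60.2 CPM, and Snap25 from 4.98 to 5068 CPM.

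Fos, an immediate early gene, took 0.149% of all counts and was at 10 CPM or more in 81% and 95.8% of warm-sensitive and insensitive cells. The immediate early list stood at percentile 92.4 for warm-sensitive cells, 2.14 to 99.8 over settings and so in either outer 2.5%, and at 95.8 for silent sensitive cells, 83.2 to 98 over settings. Quality differed by the letter in the cells' titles: the median number of genes was highest for letter A, at 5254 and lowest for letter G, at 3100.5.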
